A study of Manacus vitellinus and Taeniopygia guttata with 24 samples.

How the data were processed

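Messenger RNA was sequenced from the pectoralis (PEC), the main downstroke muscle of the wing, and from the scapulohumeralis caudalis (SH), a shoulder muscle that retracts the wing, of golden-collared manakins and zebra finches. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column and treated with DNase, and strand-specific libraries were made with a TruSeq mRNA kit. The 24 libraries fell into 8 groups of 3. In the manakin, the +T group had a testosterone implant and the -T group a blank one. In the zebra finch, per the labels' protocols, the antiandrogen drug flutamide or a blank was implanted first and all birds were given testosterone afterwards. These finch groups are called flutamide and T-only here. The titles mark the groups only as plus and minus, and minus was read as the flutamide group from the titles and the protocol together. The sample characteristics instead describe the flutamide birds as lacking testosterone, which differs from the protocol.

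The deposited values were RPKM (reads scaled to gene length and to the reads of the library) per gene, per the file headers, 1 list for each library. The headers name Ensembl release 68, and zebra finch gene identifiers were used in both species, so manakin reads were assigned to genes of another species. The submitters' processing notes name CASAVA, cutadapt and Bowtie 0.12.9 without giving their order or settings. The genome build, the mismatches allowed and the way reads were counted were not given in the sources used here. Divergence of manakin reads from zebra finch genes can lower or raise the RPKM of a gene in all manakin libraries alike, so levels compared between species carry this error. On log2(RPKM + 1), a common factor cancels only in part from treatment and muscle differences within manakin. How far divergence alters those differences, and with them the species interactions, was not tested. Only genes above 0 were listed, and an unlisted gene was read as 0. Altogether 14926 genes were listed in at least 1 library, 10959 in manakin, 13920 in zebra finch and 9953 in both species. The files did not pair identifiers with gene names, and 0 of the 14926 identifiers were found in the reference gene table at hand, which describes a manakin assembly (ASM171598v3). Genes are therefore given by identifier, at most 2 in each direction of a comparison. For the same reason the 28 gene lists fixed before the data were examined, candidate genes included, were not tested.

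Read counts were recovered from the RPKM values. Because a gene's RPKM is its reads divided by its length and by the library's read total, the totals and lengths that made all values whole were solved for. All 249311 values came out whole within a relative tolerance of 3e-13, the largest distance being 2.1e-14. The same procedure, tested on simulated data with 1500 genes, recovered 24 of 24 totals and 99.997% of the read counts. The simulated counts had no excess of even values, unlike the manakin data. Values that come out whole cannot reveal a length recovered at a fraction of its size. Of 9953 genes with a length from both species, 8955 had the same length in both. Recovered lengths had a median of 1167.5 bases, and 78.65% of them were multiples of 3. Library totals were 9742206 to 15434530 reads in manakin and 14341212 to 23458937 in zebra finch. Replicates were compared by chi-square over genes with at least 20 reads. Within groups the statistic was 42.6 to 560 per degree of freedom in the 24 pairs, so no pair differed by as little as sampling noise and none was treated as a repeated deposit of 1 library. Replicates were taken as separate birds of a group, as the labels and the bird codes of the deposited files give them.

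The tests used log2(RPKM + 1) in limma 3.58.1 (R 4.3.3), with moderated variances and Benjamini-Hochberg adjustment over the genes of a comparison. The fits of 1 species held its 12 libraries with a mean for each of the 4 groups. Comparisons of species held all 24 libraries. Genes were kept at 1 RPKM or more in at least 3 libraries of a species, and of both species in the joint fits. This filter took the place of a filter on counts that had been planned, because the files hold RPKM. A gene was called at an adjusted p below 0.05. All fold changes are on the log2(RPKM + 1) scale, which understates the change of genes at low levels. The interaction tests asked whether the treatment effect differed between muscles or species, and whether the muscle difference differed between species. "Species by" differences are manakin minus zebra finch. Values per library were compared by exact permutation tests, within birds for the muscles. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.

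Both muscles of a number carry the same bird code in the deposited files, so SH and PEC libraries of a number within a treatment were taken as the same bird. Their deviations from the group means correlated at 0.283 to 0.37 in the 6 finch birds and at -0.147 to 0.24 in the 6 manakin birds. Muscle comparisons were also fitted with the bird as a replicate block, giving 30 called genes in manakin and 3881 in zebra finch. Treatment groups hold different birds and share only numbers.

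Genes named in the text were chosen by a rule fixed before the data were examined. For treatment and muscle comparisons these were the genes past the threshold with the largest change in each direction, a minimum mean of 5 CPM computed from the recovered reads and no overlap between the sides. Where none passed in a direction, the genes with the smallest p were taken and are given as not past the threshold. For interactions and species comparisons they were the genes with the smallest adjusted p. The rule asked for gene symbols and for more genes a direction, and was applied with identifiers and 2 a direction. Before use, the procedure was tested on simulated data with 200 changed genes. At a 4-fold change it recovered 37.1% of the changed genes for manakin SH treatment, 30.6% for manakin PEC treatment, 47.5% for finch SH treatment, 60.2% for finch PEC treatment, 64.9% for the manakin muscles and 87.8% for the finch muscles. At a 2-fold change the shares were 8.1%, 9.1%, 15.2%, 14.4%, 24.7% and 42.1% in that order. Of 4-fold interactions of treatment and muscle, 7.3% were recovered in manakin and 29.3% in zebra finch. False calls, over both sizes of change, were 4 of 48 calls in manakin SH treatment and 3 of 42 in PEC. In finch they were 4 of 66 and 4 of 77. The muscles gave 7 of 94 in manakin and 10 of 136 in finch. Treatment by muscle gave 1 of 8 and 1 of 30. Species by treatment gave 5 of 46 in SH and 4 of 40 in PEC, and species by muscle 13 of 98. Species gave 28 of 157 in SH and 26 of 135 in PEC. Only in finch treatment by muscle was the false share below the adjusted p threshold.

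Alternatives fixed before the data were examined were quantile scaling, no filter and a stricter filter of 5 RPKM, a pseudocount of 0.1, the replicate number or bird as a block, leaving out each library, fits on only the libraries compared, and muscle or species comparisons within 1 treatment. Median-ratio scaling, limma-voom on the recovered reads, limma array weights and leaving out the manakin SH +T library 2 from comparisons it enters only through the shared variance were chosen after seeing the data.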

Results

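RNA was profiled in the wing muscles of 2 bird species to ask how androgens shape muscle gene expression. The golden-collared manakin (Manacus vitellinus) is a tropical bird whose males perform an acrobatic wing display, and the zebra finch is a songbird without such a display. In each species 6 birds gave both the pectoralis (PEC) and the scapulohumeralis caudalis (SH), 3 birds in each treatment group. Manakins carried testosterone (+T) or a blank implant (-T). Zebra finches all received testosterone, either after a blank (T-only) or after the antiandrogen drug flutamide (flutamide). The 12 manakin libraries held 7807541 to 13572186 reads in genes and listed 8925 to 10094 genes. The 12 finch libraries held 9644975 to 16487223 reads in genes and listed 10790 to 12109 genes. With 3 birds in a group, an exact permutation test of a treatment on 1 value cannot give a p below 0.1.

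A few transcripts made up much of the signal in both muscles, and less so in SH. The 20 most abundant genes of a library took 31.5% of all RPKM in manakin SH and 35.4% in manakin PEC, and were lower in SH in 6 of 6 birds (exact paired permutation test within birds, two-sided p = 0.0312, the smallest it can give, adjusted p = 0.225 over 36 tests). In zebra finch the shares were 43.4% in SH and 47.2% in PEC, with SH higher in 1 of 6 birds (exact paired permutation p = 0.0938, adjusted p = 0.3). Of the 20 genes with the highest mean in each species, 7 were shared. More genes were listed in finch SH than in finch PEC, 11620 against 11060 on average and in 6 of 6 birds (exact paired permutation p = 0.0312, adjusted p = 0.225). In manakin the averages were 9676 and 9194, with SH higher in 5 of 6 birds (exact paired permutation p = 0.0625, adjusted p = 0.3). Depth was not removed from these counts. Manakin SH libraries had 13610000 reads on average against 12210000 in PEC, with SH higher in 5 of 6 birds. In finch the averages were 16950000 in SH and 17930000 in PEC, with SH higher in 2 of 6 birds. None of these library-level tests passed after adjustment. That outcome was fixed by the numbers of birds and tests: the smallest p values that the 36 tests can give are too large to pass it.

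**Figure D1:**
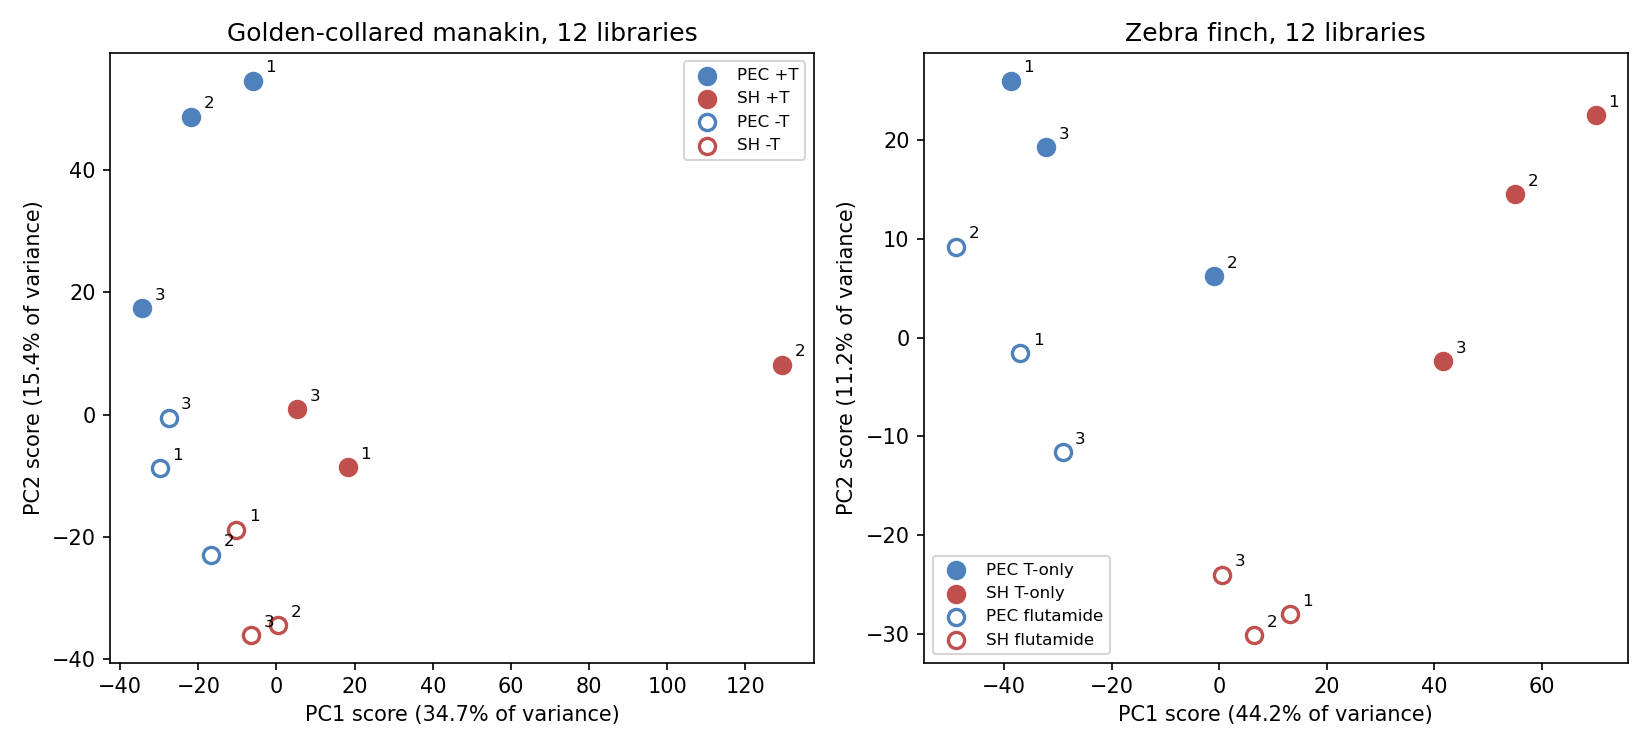
Scores of the 12 libraries of each species on the first and second principal components of log2(RPKM + 1), with SH in red and PEC in blue, and +T or T-only as filled and -T or flutamide as open circles; numbers are birds. The manakin SH +T library 2 sits at 129.3 on a component with 34.7% of the variance, while finch SH T-only libraries lie at 41.6 to 70 on a component with 44.2%.

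The manakin SH +T library 2 stood apart from all others. It held 349 genes at 10 RPKM or more and over 8-fold above every other manakin library, against 0 to 4 in the other 11 libraries. These genes took 18.9% of its RPKM. Its correlation with the other +T SH libraries across genes was as low as 0.79, and 87.93% of its reads fell in genes, against 73.64% to 80.56% in the other 11 libraries. It was kept in all main comparisons.

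Few genes differed between +T and -T past the threshold in manakin SH. ENSTGUG00000017344 was at 30.6 ± 23 RPKM (SD, n = 3) in +T and was listed in none of the 3 -T libraries (limma adjusted p = 0.0136). ENSTGUG00000009958 was lower in +T, at 0.477 ± 0.479 RPKM against 10.6 ± 1.27 in -T (SD, n = 3 each), a log2 difference of -3.02 ± 0.41 (SE, limma adjusted p = 0.0354). Both fall outside the naming rule and were chosen after their values were seen. They were the 2 genes called of 8989 tested, and 1036 genes were below an unadjusted p of 0.05. The count was 1 with median-ratio scaling, 0 with limma-voom on the recovered reads (1001 below unadjusted 0.05) and 321 with limma array weights. It was 0 without the -T library 1 or 3, 1 without the -T library 2, that gene being neither of these, 4 without the +T library 1 or 2 and 20 without the +T library 3. ENSTGUG00000009958 lost its call in 11 of 15 alternatives, among them no filter (0.0564), the replicate block (0.0596), median-ratio scaling (0.0612) and leaving out the +T library 1 (0.0675) or 2 (0.0506) or any 1 -T library (0.104 to 0.182). ENSTGUG00000017344 lost its call in 5 of 15: with limma-voom, in a fit on the 6 libraries compared and without any 1 -T library. The adjusted p went up to 0.255 for both. Over all genes tested, the median log2 difference was 0.11 and moved to 0.03 with median-ratio scaling, to -0.004 without the +T library 2, 0.22 without the +T library 3 and 0.05 without the -T library 1.

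In manakin PEC, 12 genes were called higher and 24 lower in +T, of the 8989 tested. ENSTGUG00000005022 rose from 100 ± 62.7 to 1654 ± 697 RPKM (SD, n = 3 each), a log2 difference of 4.13 ± 0.66 (SE, limma adjusted p = 0.0279), and was 4.36 with median-ratio scaling. ENSTGUG00000006540 rose from 37.0 ± 13.6 to 698 ± 502 RPKM (log2 3.99 ± 0.71, adjusted p = 0.0373). ENSTGUG00000000287 fell from 66.6 ± 14.3 to 6.02 ± 5.44 RPKM (log2 -3.56 ± 0.63, adjusted p = 0.0373), and ENSTGUG00000010681 fell from 43.1 ± 9.28 to 3.27 ± 1.29 RPKM (log2 -3.39 ± 0.47, adjusted p = 0.0188). The called genes that rose had a median log2 change of 2.88, those that fell one of -2.36, and all 36 changed at least 2-fold.

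Across all genes the median was lower in +T PEC, by -0.18. With median-ratio scaling that median was 0 and the PEC calls were 22 higher and 21 lower, against 12 and 24 as deposited. Quantile scaling left 3 higher and 1 lower, limma-voom 16 genes and array weights 228. The count was 0 without the PEC +T library 1 or the -T library 2 or 3, 2 without the -T library 1, 3 without the +T library 2, 117 without the +T library 3, and 168 without the SH +T library 2, which enters only through the shared variance. Each of the 4 named genes lost its call when the +T library 1 or 2 or any 1 -T library was left out, with adjusted p up to 0.172, and with quantile scaling (0.0558 to 0.0654). In a fit on the 6 libraries compared, ENSTGUG00000005022 (0.0541), ENSTGUG00000006540 (0.0608) and ENSTGUG00000000287 (0.0795) lost theirs. ENSTGUG00000006540 and ENSTGUG00000000287 also did so with no filter, the first with limma-voom (0.138) and the second with a pseudocount of 0.1 (0.058).

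The treatment differences of the manakin muscles were correlated across 8989 genes (r = 0.404, rho = 0.361, genes not being independent replicates), with 58.2% of genes of the same sign. Both muscles came from the same 6 birds, which by itself can make the differences agree. The other 9 splits of these birds gave r from -0.026 to 0.315 (median 0.103), and 10 splits are too few to tell the real one from chance at 0.05. Of the PEC calls, 11 of 12 higher and 23 of 24 lower genes had the same sign in SH. ENSTGUG00000010681, for one, differed by -2.98 in SH (limma adjusted p = 0.0523). The test of treatment by muscle called 0 genes with limma (459 below unadjusted 0.05; voom 0 and 415), so the smaller count in SH is not shown to be a smaller effect. ENSTGUG00000000287 came nearest, with a difference between muscles of 6.13 ± 0.89 (SE, adjusted p = 0.148). In SH it was at 8.65 ± 8.66 RPKM in +T and 0.257 ± 0.0987 in -T. It passed with the bird as a replicate block, where 1 gene was called (adjusted p = 0.0345), with array weights (2 genes), without the PEC +T library 1 (1 gene) and without the SH +T library 2 (2 genes). Its adjusted p over 20 alternatives went up to 0.824. Leaving out the SH -T library 2 gave 1 called gene.

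SH and PEC of the manakin differed in 72 of 8989 genes, 63 higher and 9 lower in SH. ENSTGUG00000011307 was at 92.5 ± 64.6 RPKM in SH and 0.993 ± 1.55 in PEC (SD, n = 6 each; log2 5.51 ± 0.47, limma adjusted p = 0.000159). ENSTGUG00000007447 was at 140 ± 95.8 and 3.16 ± 3.85 RPKM (log2 5.43 ± 0.37, adjusted p = 3.83e-05). ENSTGUG00000006008, among the most abundant PEC transcripts at 20340 ± 7252 RPKM, was at 203 ± 182 in SH (log2 -7.41 ± 0.78, adjusted p = 0.000826). ENSTGUG00000007670 was at 15263 ± 5194 in PEC and 463 ± 295 in SH (log2 -5.78 ± 0.85, adjusted p = 0.0094). ENSTGUG00000007447 lost its call with limma-voom (adjusted p = 0.0641) and ENSTGUG00000007670 within -T birds (0.423), each in 1 of 22 alternatives.

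Manakin SH had a median over all genes 0.27 above PEC. With median-ratio scaling the split was 22 higher and 16 lower, and with quantile scaling 16 and 14. With the bird as a replicate block the count was 30, 23 higher and 7 lower, with 21 of the 30 also called without the block. It was 26 with limma-voom, 34 with no filter, 1020 with array weights, 14 within -T birds and 16 within +T birds. The count fell when any 1 library other than SH +T library 2 or 3 was left out, to 50 without the SH +T library 1, to 24 without the PEC -T library 1, 37 without library 2 and 29 without library 3 of that group, to 42, 35 and 36 without the PEC +T libraries 1, 2 and 3, and to 34, 35 and 31 without the SH -T libraries 1, 2 and 3. It rose to 175 without the SH +T library 2 and to 237 without the SH +T library 3.

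In zebra finch SH, 589 genes were higher and 6 lower in T-only than in flutamide of 9606 tested. ENSTGUG00000018460 was at 54.7 ± 60.2 RPKM in T-only and 0.186 ± 0.322 in flutamide (SD, n = 3 each; log2 5.0 ± 0.56, limma adjusted p = 0.00287). ENSTGUG00000008939 was at 259 ± 102 and 22.2 ± 26.3 RPKM (log2 4.06 ± 0.77, adjusted p = 0.00861). ENSTGUG00000012446 was lower, at 4.95 ± 0.477 against 18.4 ± 7.39 RPKM (log2 -1.65 ± 0.45, adjusted p = 0.0446), as was ENSTGUG00000013262, at 6.89 ± 2.79 against 16.8 ± 6.08 RPKM (log2 -1.18 ± 0.30, adjusted p = 0.0334). The called genes that rose had a median log2 change of 1.56, 559 changed at least 2-fold and 135 at least 4-fold. Of them 343 averaged under 5 RPKM, and 3 were at 500 RPKM or more.

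In T-only SH the median of all finch genes was higher by 0.22 than in flutamide SH. With median-ratio scaling, where it was -0.002, 286 genes were higher and 29 lower, and with quantile scaling 248 and 33. Calls numbered 270 with the stricter filter, 257 with a pseudocount of 0.1, 473 with limma-voom, 1028 with array weights and 361 in a fit on the 6 SH libraries. They numbered 183 without the T-only library 1, 391 without the T-only library 2, 233 without the flutamide library 2 and 235 without the flutamide library 3. ENSTGUG00000008939 lost its call without the T-only library 1 (adjusted p = 0.0501). ENSTGUG00000012446 lost its call in 10 of 15 alternatives: without any 1 of the 6 libraries (adjusted p up to 0.153), with no filter (0.0754), the stricter filter (0.0532), a pseudocount of 0.1 (0.0676) and limma-voom (0.0531). ENSTGUG00000013262 lost its call in 7 of 15: without any 1 library except the T-only library 3 (up to 0.181), with a pseudocount of 0.1 (0.054) and in the fit on the 6 SH libraries (0.0866). Only 1 gene was lower with the stricter filter.

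In zebra finch PEC, limma called 0 genes, with 514 below an unadjusted p of 0.05, and limma-voom 0, with 517. The genes with the smallest p did not pass. ENSTGUG00000006621 was at 10 ± 1.71 RPKM in T-only and 3.15 ± 0.872 in flutamide, and ENSTGUG00000018740 at 169 ± 94.8 and 41.5 ± 9.22 RPKM (SD, n = 3 each; limma adjusted p = 0.181 and 0.255). ENSTGUG00000003897 was at 33.1 ± 1.39 and 87 ± 16.3 RPKM, and ENSTGUG00000012207 at 120 ± 22.9 and 492 ± 131 RPKM (limma adjusted p = 0.181 for both). The treatment differences of the finch muscles correlated across 9606 genes (r = 0.445, rho = 0.437), and 486 of the 589 genes higher in T-only SH were also higher in T-only PEC. As both muscles came from the same birds, this agreement is not by itself a shared response: the other 9 splits of the 6 birds gave r from 0.25 to 0.42 (median 0.366). The test of treatment by muscle called 0 genes with limma (706 below unadjusted 0.05; voom 0 and 442). With the bird as a replicate block, limma called 0, with 960 below unadjusted 0.05 and a smallest adjusted p of 0.101. The response of SH is therefore not shown to differ from that of PEC. Without the block, the gene nearest to the threshold was ENSTGUG00000018460, with a difference of 5.05 ± 0.79 (SE, adjusted p = 0.19). That gene passed without the SH T-only library 1 (adjusted p = 0.00581, 1 gene called) and without library 2 (0.0139, 3 genes called), and 1 gene was called without library 3.

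**Figure D2:**
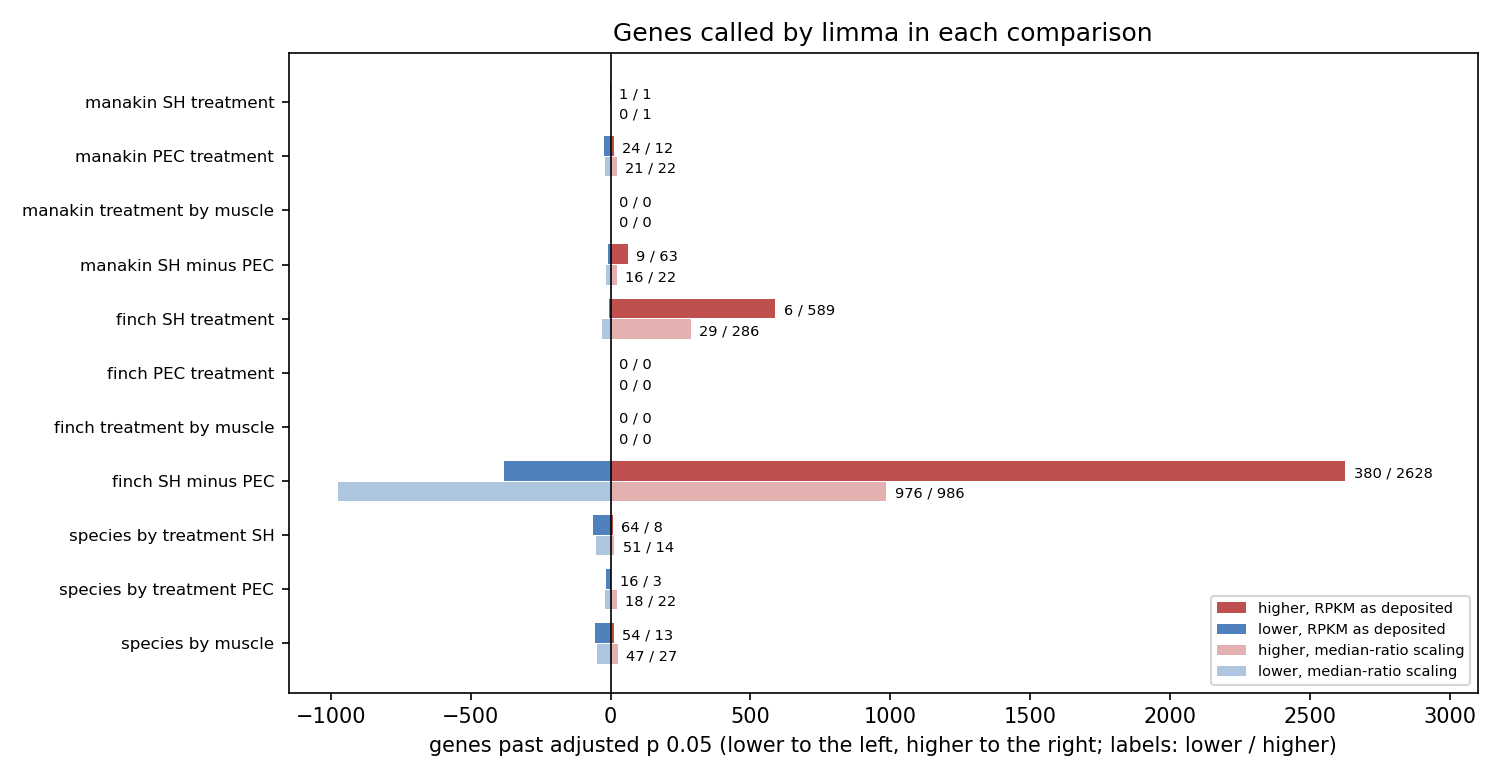
Number of genes past an adjusted p of 0.05 in limma for 11 comparisons, higher to the right of 0 and lower to the left, with the RPKM as deposited (dark bars) and with median-ratio scaling (light bars). The finch muscle comparison goes from 2628 higher and 380 lower to 986 and 976, and finch SH treatment from 589 and 6 to 286 and 29.

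SH and PEC of the zebra finch differed in 3008 of 9606 genes, 2628 higher and 380 lower in SH. ENSTGUG00000010713 was at 787 ± 252 RPKM in SH and 3.19 ± 2.4 in PEC (SD, n = 6 each; log2 7.73 ± 0.38, limma adjusted p = 7.06e-08). ENSTGUG00000006624 was at 43.5 ± 12.9 and 0.0354 ± 0.0866 RPKM (log2 5.37 ± 0.22, adjusted p = 1.27e-08). ENSTGUG00000006008 was again far lower in SH, at 777 ± 527 against 23451 ± 4940 RPKM in PEC (log2 -5.18 ± 0.38, adjusted p = 4.05e-06), and ENSTGUG00000004856 was at 1.6 ± 1.25 against 45.8 ± 17.8 RPKM (log2 -4.25 ± 0.32, adjusted p = 4.32e-06). Of 134 genes at 500 RPKM or more, 13 were higher and 48 lower in SH, while of 4156 genes under 5 RPKM 1117 were higher and 57 lower. With median-ratio scaling these counts were 6 and 72, and 474 and 126.

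The number and balance of the finch muscle calls depended on the scaling. Finch SH had a median 0.34 above PEC, and median-ratio scaling gave 986 higher and 976 lower, quantile scaling 893 and 753. All 3008 genes had the same sign with both scalings, and 1366 of them were called with the first and 1196 with the second. Within flutamide birds 72 genes were called, and within T-only birds 1855.

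The muscle differences of the species were correlated across the 7237 genes tested in both (r = 0.466, rho = 0.459), with 76.6% of genes of the same sign and 67.8% with median-ratio scaling. A lean of both species towards SH by itself raises this share. In manakin, 73.9% of these genes were higher in SH as deposited and 54.1% with median-ratio scaling. Of the genes called in both, 36 were higher in SH in both species, against 16.02 expected for independent lists, 3 were lower in both, against 0.21, and 2 went opposite ways. With median-ratio scaling 13 were higher in both (2.02 expected) and 4 lower (1.09 expected). Treatment differences were close to uncorrelated between species, at r = 0.036 in SH and r = -0.025 in PEC, the treatments themselves not being alike.

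**Figure D3:**
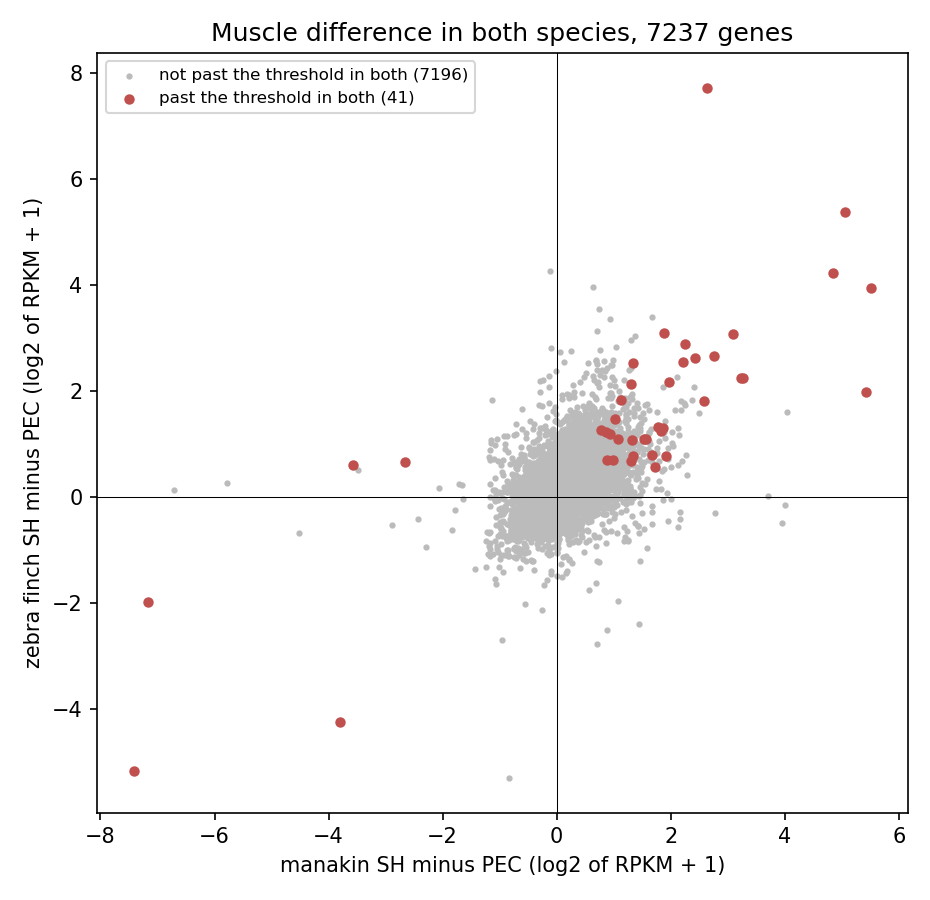
The log2 difference between SH and PEC in manakin (horizontal axis) and zebra finch (vertical axis) for each of 7237 genes, on the log2(RPKM + 1) scale, with genes past the threshold in both species in red. Of the 41 red genes, 36 are higher in SH in both species and 3 lower in both.

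The muscle difference itself differed between species in 67 of 7237 genes, 13 higher and 54 lower in manakin. ENSTGUG00000010713 rose from 3.19 to 787 RPKM between PEC and SH in the finch, over both treatments. In manakin it rose from 846 ± 215 to 5092 ± 869 RPKM in -T birds. In +T birds the rise was from 1345 ± 991 to 7401 ± 3005 RPKM (SD, n = 3 each). Over both treatments the difference of differences was -5.09 ± 0.57 (SE, limma adjusted p = 6.93e-05). ENSTGUG00000001343 differed by -2.91 ± 0.38 (adjusted p = 0.000306), ENSTGUG00000010842 by 3.39 ± 0.57 (adjusted p = 0.0051) and ENSTGUG00000007447 by 3.45 ± 0.63 (adjusted p = 0.00958). The last was not called by limma-voom (adjusted p = 0.208, range over 32 alternatives up to that value). The split was 27 and 47 with median-ratio scaling and 25 and 46 with quantile scaling. With the bird as a replicate block, 99 genes were called. limma-voom called 33 genes and array weights 185, and the count fell to 44, 41 and 43 without library 1 of the manakin PEC +T, PEC -T and SH -T groups. Among finch libraries it was 42 without PEC T-only 1, 28 without SH T-only 1, 36 and 44 without PEC flutamide 1 and 2, and 40, 31 and 44 without SH flutamide 1, 2 and 3.

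The androgen manipulations were compared between species as +T minus -T in manakin against T-only minus flutamide in zebra finch, which are different treatments. In SH the effect differed for 72 of 7237 genes, 8 higher and 64 lower in manakin. ENSTGUG00000008853 was at 185 ± 188 RPKM in +T and 7.21 ± 8.04 in -T manakins, and at 7.32 ± 1.61 in T-only and 28.6 ± 20.3 in flutamide finches (difference of 6.18 ± 1.05, SE, n = 3 each, limma adjusted p = 0.00531). ENSTGUG00000003909 differed by 1.38 ± 0.26 (adjusted p = 0.0114) and missed the threshold without the manakin SH -T library 2 (0.0507). ENSTGUG00000000398 differed by -5.22 ± 0.64 (adjusted p = 0.000336), at 28.6 ± 7.11 RPKM in T-only and 1.97 ± 0.785 in flutamide finches and at 4.79 ± 3.17 in +T and 18.5 ± 5.66 in -T manakins. ENSTGUG00000013543 differed by -3.54 ± 0.51 (adjusted p = 0.00204). The median of all genes differed by -0.13 (-0.24 without the manakin SH +T library 2, -0.03 without library 3 of that group and -0.08 without the finch SH T-only library 1), and median-ratio scaling gave 14 higher and 51 lower. The count was 33 with the stricter filter or limma-voom, 43 with a pseudocount of 0.1 and 704 with array weights. Without the manakin SH -T libraries 1, 2 and 3 it was 41, 21 and 113, without the finch SH T-only libraries 1 and 3 it was 30 and 113, and without the SH flutamide library 2 or 3 it was 35.

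In PEC the effect differed between species for 19 genes, 3 higher and 16 lower in manakin. ENSTGUG00000005022 was at 39.8 ± 13.4 RPKM in T-only and 37.5 ± 4.14 in flutamide finches, against its rise in manakin PEC (difference of 4.10 ± 0.75, SE, n = 3 each, limma adjusted p = 0.0161). ENSTGUG00000008853 differed by 5.24 ± 1.05 (adjusted p = 0.0269), ENSTGUG00000010681 by -3.71 ± 0.55 (0.00612 adjusted) and ENSTGUG00000006621 by -3.02 ± 0.48 (0.00612 adjusted). ENSTGUG00000008853 lost its call (adjusted p up to 0.0942) when any 1 manakin PEC library other than +T 3 was left out, or the finch PEC libraries T-only 1, T-only 2, flutamide 2 or flutamide 3, and ENSTGUG00000005022 in 3 alternatives (without the manakin PEC +T library 1 or 2, or the finch PEC T-only library 3). The median of all genes differed by -0.27 (-0.15 without the finch PEC T-only library 2), and the split was 22 higher and 18 lower with median-ratio scaling and 6 and 9 with quantile scaling. The count was 33 with the stricter filter and 89 with array weights. Without the manakin PEC +T libraries 1, 2 and 3 it was 12, 10 and 100, without the PEC -T libraries 1 and 3 it was 12 and 10, without the finch PEC T-only libraries 1 and 3 it was 32 and 9, without the PEC flutamide library 2 it was 11, and without the manakin SH +T library 2 it was 65.

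Levels differed between the species in 4377 of 7237 genes in SH and in 4554 in PEC. ENSTGUG00000005002 was at 15450 ± 1655 RPKM in T-only finch SH and at 26.9 ± 14.8 in +T manakin SH (SD, n = 3; log2 over both treatments -9.55 ± 0.26, SE, limma adjusted p = 4.56e-17), and in PEC at 13548 ± 1691 and 13.7 ± 7.72 (log2 -10.09 ± 0.26, limma adjusted p = 1.6e-17). ENSTGUG00000004712 was higher in manakin in both muscles (log2 4.81 ± 0.14 in SH and 4.64 ± 0.14 in PEC). ENSTGUG00000011617 was higher in manakin SH (7.30 ± 0.20) and ENSTGUG00000010674 in manakin PEC (7.49 ± 0.21), while ENSTGUG00000010443 was lower in manakin by -7.89 ± 0.23 in SH and -7.90 ± 0.23 in PEC. The median of all genes was 0.52 higher in manakin in SH and 0.62 in PEC. The SH split was 3362 higher and 1015 lower as deposited and 2019 and 2097 with median-ratio scaling, and the PEC split 3630 and 924, and 2028 and 2186. Because manakin reads were assigned to finch genes, these differences hold sequence divergence as well as expression.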

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

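Of the tests reported here, those of library depth, of finch reads, of the whole bird, of a wrong sample, of the scaling and of abundant pectoralis transcripts, of read ratios and odd counts, and all counts of other groupings were chosen only after the result was seen; the dilution test, the test by gene length and the other 2 on pectoralis tissue were fixed before their values were known.

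The effect of the androgen manipulation differed between manakin and finch, by a test of the difference, for 72 genes in SH and 19 in PEC. The muscle difference did so for 67 genes. The manipulations were not alike, so the treatment counts cannot tell a difference of species from one of treatment. How far the assignment of manakin reads to finch genes enters the treatment and muscle counts was not tested. In SH the named genes were ENSTGUG00000008853 (6.18), ENSTGUG00000003909 (1.38), ENSTGUG00000000398 (-5.22) and ENSTGUG00000013543 (-3.54), as log2 differences of manakin minus finch. In PEC they were ENSTGUG00000005022 (4.1), ENSTGUG00000008853 (5.24), ENSTGUG00000010681 (-3.71) and ENSTGUG00000006621 (-3.02). For the muscles they were ENSTGUG00000010842 (3.39), ENSTGUG00000007447 (3.45), ENSTGUG00000010713 (-5.09) and ENSTGUG00000001343 (-2.91). Of 100 regroupings of the birds within species, 5 gave as many genes as the real one for SH (72, highest other 176) and 5 for PEC (19, highest other 192). This is not used, since it does not hold the effect of each species fixed: with the finch labels alone reversed, 108 and 28 genes were called. A replacement, added after those counts were seen, first removed the treatment effect common to the species. There 1 of 100 gave as many for SH (72, highest other 9) and 1 of 100 for PEC (19, highest other 3), the real one each time, which excludes chance at 0.05 in this test alone. For the muscles the 12 birds were regrouped across species within treatment label, with the bird as a replicate block. There 1 of 100 regroupings gave as many genes, the real one (99, highest other 2), which excludes chance at 0.05 for that count. Swapping muscle labels within birds gave 2 of 100 for the count of 67 (highest other 260), but is not used here, since it does not hold the muscle effect of each species fixed (2883 with all finch labels reversed).

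The other comparisons were regrouped in the same way. With 10 splits of 6 birds a share under 0.05 is out of reach. The real split alone gave as many genes in 1 of 10 for manakin SH treatment (2, highest other 1), manakin PEC treatment (36, highest other 1) and finch SH treatment (595, highest other 1). All 10 gave 0 or more for manakin treatment by muscle (highest other 0), finch PEC treatment (highest other 3) and finch treatment by muscle (highest other 0). Swapping muscle labels within birds, 1 of 32 gave as many genes in manakin (72, highest other 3) and 1 of 32 in finch (3008, highest other 766). Splitting libraries within treatment gave 1 of 100 in each, with the same highest values, and 1 of 100 for species SH (4377, highest other 3082) and species PEC (4554, highest other 2671). Chance is excluded at 0.05 for these muscle and species counts. For the species counts this does not bear on expression, since assigning manakin reads to finch genes can by itself set the species apart.

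The manakin SH +T library 2, with its 349 genes over 8-fold above all others, was weighed against 5 explanations. Depth is argued against by the library of nearest total, SH -T 1, which held 2 such genes, and zebra finch reads by its correlation of 0.53 with the finch SH mean, below the 0.603 to 0.63 of the other 11 manakin libraries. A difference of the whole bird is argued against only if the labels of its SH and PEC libraries are right. Chosen without the PEC library labelled as the same bird, 352 genes were over 8-fold above the other 10 libraries. Their median log2 ratio in that PEC library to the other +T PEC libraries was -0.076. A wrong sample or label stays open, bearing on every SH +T value: its deviations correlated with that PEC library at 0.051, below another +T bird's 0.197, but manakin libraries matched their own bird best in 2 of 6. RNA of other cells diluting that of muscle stays open: the 100 most abundant SH genes were lower by a median of -0.82 with an interquartile range of 0.93, wider than the 0.663 of the next library but not by the 2 times that would have ruled it out, and an effect of testosterone is untested.

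The near one-way calls of finch SH treatment, 589 of 595 higher in T-only, were weighed against the scaling and against pectoralis tissue in the flutamide SH samples. Scaling alone is argued against, since 90.8% of the calls were higher with median-ratio scaling. Pectoralis tissue as the whole cause is argued against by 8 genes abundant in T-only PEC and at least 4-fold lower in T-only SH: in flutamide SH they reached a median of 18.6% of their flutamide PEC level (1.43% to 48.7%), while lowering the called genes by their median of 1.563 would need 66.2% pectoralis RNA. By themselves, 2 earlier tests did not decide: 13 genes at least 8-fold higher in SH than PEC differed by a median of 1.225, and flutamide PEC was at or above flutamide SH in 18.8% of the 589 genes, both between the bounds set in advance. An effect of flutamide in SH, which the design names, stays open as a hypothesis, and is not the only one left. Higher in T-only SH were 79.4% of genes under 5 RPKM and 26.1% of those at 500 RPKM or more. A different make-up of the T-only SH samples was not tested.

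Read counts in manakin libraries were mostly even, at 60.37% to 71.76%, against 48.24% to 49.86% in finch. Genes with 2 reads outnumbered those with 1 read by at least 3.207 times in every manakin library, against at most 1.188 in finch, which restates the excess. Counting both mates of a fragment as reads is a candidate explanation. Its test by gene length assumed that mates are lost more often at the ends of short genes, which was not measured. Among genes with 1 to 10 reads, even counts were more frequent in the longest than the shortest of 3 length classes in manakin. The difference was at least 9.72 percentage points in the manakin libraries and at most 8.35 in finch. Lengths recovered at 2 times their size are argued against, since at least 28.24% of the manakin counts were odd. The reads would then overstate the number of fragments, and no biological explanation was tested.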

How the results depend on the processing

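Median-ratio scaling, limma-voom on recovered reads, array weights and dropping manakin SH +T library 2 where it enters only the shared variance were chosen after seeing the data; other alternatives were fixed before. Species counts stayed within 1.5 times in all alternatives run, as did finch PEC treatment at 0. The counts of called genes that moved are given here, and the cause was not tested. Manakin SH treatment (2) was 10 with the stricter filter, 1 with pseudocount 0.1, 1 with the replicate block, 1 with median-ratio scaling, 0 with voom, 321 with array weights and 0 in a fit on its 6 libraries. Manakin PEC treatment (36) was 4 with quantile scaling, 21 unfiltered, 16 with voom, 228 with array weights and 17 in its own 6 libraries. Manakin treatment by muscle (0) was 1 with the replicate block and 2 with array weights. Manakin SH against PEC (72) was 30 with quantile scaling, 34 unfiltered, 30 with the replicate block, 38 with median-ratio scaling, 26 with voom, 1020 with array weights, 14 within -T and 16 within +T. Finch SH treatment (595) was 281 with quantile scaling, 270 with the stricter filter, 257 with pseudocount 0.1, 315 with median-ratio scaling, 1028 with array weights and 361 in its 6 libraries. Finch treatment by muscle was 1 unfiltered. Finch SH against PEC (3008) was 1646 with quantile and 1962 with median-ratio scaling, 72 within flutamide and 1855 within T-only. Species by treatment in SH (72) was 33 with the stricter filter, 43 with pseudocount 0.1, 33 with voom and 704 with array weights. In PEC (19) it was 33 with the stricter filter, 32 with the replicate block, 40 with median-ratio scaling and 89 with array weights. Species by muscle (67) was 33 with voom and 185 with array weights. Leaving out 1 library gave 0 to 20 for manakin SH treatment, 0 to 168 for PEC treatment, 0 to 2 for treatment by muscle and 24 to 237 for the muscles, and in finch 183 to 722, 0 to 0, 0 to 3 and 2150 to 3848. It gave 21 to 113, 9 to 100 and 28 to 93 for the species interactions in SH, PEC and muscle, and 4155 to 4490 and 4350 to 4781 for species in SH and PEC. Where an arm kept 2 libraries, the spread was shared with the other groups. The replicate block moved no other count by more than 1.5 times. For treatments it joins different birds that share a number (correlations of deviations -0.243 to 0.072), and finch libraries of a bird each matched their own number best in 6 of 6, manakin in 2 of 6. No named gene reversed. The gene lists gave no value in any setting, as no identifier matched a name, and a count test of the RPKM was not run.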

Other observations

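Both tests of this part were chosen after the results they measure were seen. Some genes were abundant in 1 species and not listed in the other. Of 706 genes at 50 RPKM or more in all 12 finch libraries, 155 were listed in no manakin library, and of 919 genes at that level in all 12 manakin libraries, 46 were listed in no finch library. Manakin reads were assigned to finch genes, so an unlisted gene need not be unexpressed, and how far this enters the counts was not tested. Within a species the leading transcripts were shared between groups, with 11 of the 20 most abundant genes common to the 4 manakin groups and 17 of 20 in the finch.

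A first hypothesis was that the muscle difference is shared by the species. Across 7237 genes the correlation was 0.466, and 1 of 100 label swaps within birds gave one as large, the real labels included (highest other 0.447). The swaps break up the muscle effect of each species, so they exclude at 0.05 only muscle labels that carry no effect. Whether the muscle effects of the species are related cannot be decided by them, and the hypothesis stays open.

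A second hypothesis was that the androgen effect in finch SH runs along the muscle difference seen in manakin, whose libraries it does not share. The correlation across genes was 0.228, 0.251 with median-ratio scaling, and 353 of the 426 genes called higher in T-only finch SH and tested in manakin were higher in manakin SH than PEC, 155 of 212 with median-ratio scaling. Of all 7237 genes tested in both, 73.9% were higher in manakin SH as deposited and 54.1% with that scaling, against 82.9% and 73.1% of the called genes, so much of the first share is that of all genes. Of the 10 splits of the finch birds 1 gave a correlation as large, the real one (highest other 0.207), and 10 splits are too few for a share under 0.05. Finch PEC treatment correlated with the manakin muscle difference at 0.076. The reverse did not show the pattern: the finch muscle difference correlated with manakin SH treatment at 0.046 (-0.007 without the SH +T library 2) and with manakin PEC treatment at -0.05.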
